A study of Arabidopsis thaliana with 6 samples.

How the data were processed

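Polyadenylated RNA from immature flower buds (inflorescence stages 1 to 12) of Arabidopsis thaliana, ecotype Columbia, was sequenced as full-length PCR-cDNA on an Oxford Nanopore MinION. Per the labels' protocols, plants grew at 22 °C with 16 h of light per day, and 50 ng of poly(A) RNA entered each reverse transcription. The libraries of 5 genotypes (wt, ddm1, ddm1 rdr6, ddm1 polV and ddm1 rdr6 polV replicate A) were amplified with 14 PCR cycles and sequenced together in round 1. Replicate B of ddm1 rdr6 polV was amplified with 13 cycles and sequenced alone in round 2, at a higher depth per the labels. Per the labels, RNA of wt was extracted with TriZOL and RNA of the mutants with TriZOL LS. The labels do not say whether the replicates A and B came from separate plants.

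The authors deposited, for each library, a set of transcript models with their exons and a list pairing each model with identifiers of annotated transposable elements (TEs). The submitters' processing notes name minimap2 as the aligner and TAIR10 as the genome build, and the source column of the model files names pinfish, a tool that clusters long reads into transcript models. Versions, cluster settings and the rule by which models were paired with TEs are not given in the sources used here. Each model name ends in a whole number of at least 10. It was read here as the number of reads in the model's cluster, following how pinfish names its clusters, which the files do not state. The files give no library totals, so the size of any depth difference is unknown. A locus without a model had no cluster of 10 reads or more, which is not the same as no transcript, and cluster reads are not all reads of a locus. The files pair TE identifiers with no family or superfamily names.

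Groups and replicates were taken from the sample titles. Coordinates are those of the deposited models (TAIR10, 1-based). The reference sequence and annotation used here are TAIR10.1, and the match of both was checked through splice sites. Of 509 distinct introns, 501 (98.4%) began with GT and ended with AG on the model's strand, 3 were GC-AG, and 0 models ran past a chromosome end. Models whose exons overlapped by at least 1 bp on the same strand, in any library, were merged into loci, named by their first TE identifier. Gene symbols and gene types came from the reference annotation by overlap with an exon or an intron of a gene on the same strand. Pericentromeric bins were those of 500 kb with less than 40% of bases in protein-coding genes, 51 of 240 bins and 21.4% of the nuclear genome.

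Superfamily was approximated by a translated BLAST+ (2.17.0) search of each spliced model against 148 reference proteins whose names state a TE type (e-value 1e-05). Only 130 of 829 models (15.7%) matched, at 68 of 344 loci. Loci were also joined into sequence groups when their models aligned at 80% identity or more over at least 80% of the shorter one and at least 80 nt. These groups stand in for families, and are named by a lead locus. The rule for named elements, fixed before the data were examined, took every TE with a model in wt, the 10 families with most models per mutant library, up to 10 loci found in all 5 mutant libraries ranked by their models in replicate B, and up to 5 models with most exons and 5 longest models per mutant library that overlapped a model of another library. It also listed TE families by name (ATHILA, ATCOPIA93, ATENSPM3, VANDAL21 and others) and the genes DDM1, RDR6 and NRPE1. The named families could not be matched to the identifiers, and the files hold no values for those genes, so the genotypes were not checked through the mutated genes. Sadhu elements, QQS and loci with unusual read ratios were chosen after their values were seen.

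Numbers of models have exact Poisson 95% intervals, and ratios of numbers were tested with the exact conditional binomial test. Shares have exact Clopper-Pearson 95% intervals and were compared with Fisher's exact test. Median spliced lengths were compared by permutation with 100000 resamples. All tests were two-sided, with Benjamini-Hochberg adjustment over 7 pairs for numbers, 4 pairs for shares and lengths, and 32 class tests for composition. Intervals cover counting error only, since PCR reads carried no molecular identifiers and models of 1 library are not independent samples. Each genotype had 1 library in round 1, so every test compares libraries, not genotypes. Tests of numbers, shares and lengths between libraries treat each library's models as an independent set, although many loci are shared. Open reading frames were the longest from ATG to stop on the model's strand. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, biopython 1.88 and matplotlib 3.10.9. The tests were tested on simulated data with the model numbers of ddm1 (48) and ddm1 rdr6 (107). Without a difference, 3.0% of simulated pairs were called at an unadjusted p under 0.05 for the spliced share and 4% for length. A difference of 25 percentage points in the spliced share was called in 79.0%, and a 1.5-fold difference in length in 57%. Simulated models were drawn independently and without adjustment over pairs, so these rates do not carry over to the adjusted tests. Alternatives covered merging into loci, a 500 nt length minimum, intron and overlap definitions, bin definitions, and replicate B in place of A.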

Results

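Long-read cDNA libraries from immature flower buds gave 829 TE transcript models at 344 loci, paired with 382 TE identifiers. The 6 libraries covered wild type (wt) and 4 mutant genotypes: ddm1, ddm1 rdr6, ddm1 polV and ddm1 rdr6 polV. DDM1 is a chromatin remodeler needed to maintain DNA methylation over TEs. RDR6 is an RNA-dependent RNA polymerase that makes double-stranded RNA for small interfering RNAs, and Pol V is an RNA polymerase that acts in RNA-directed DNA methylation. The triple mutant had replicates A (round 1) and B (round 2), and the other genotypes had 1 library each, with no replicate check. Cluster reads summed to 136 in wt, 1212 in ddm1, 3128 in ddm1 rdr6, 4303 in ddm1 polV, 2317 in replicate A and 17106 in replicate B. These sums cover TE models only, and library totals are unknown. Per the labels, round 2 had the higher depth.

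The comparison of wt with ddm1 asked which TEs give transcripts when DDM1 is lost. The wt library held 6 TE models (exact Poisson 95% interval 2.20 to 13.1) and the ddm1 library 48 (35.4 to 63.6), a ratio of 8 (3.42 to 22.9, adjusted p = 7.6e-09, exact binomial test). Of the 44 loci in ddm1, 41 had no model in wt. The 3 loci found in both libraries had nearly equal reads, 103 in wt and 106 in ddm1 together (mean log2 ratio 0.02, SE 0.04, against 3.16 for all TE reads). This SE is taken from the spread of the 3 ratios and leaves out counting error, as do the SEs at wt loci given below. The other 3 wt loci had 11 reads each in wt and no model in ddm1, so they do not enter this ratio. With multi-exon models only, the ratio was 18, from 1 model in wt. The wt library also differed from the mutants in its RNA extraction. Library totals are unknown, so depth may also enter the ratio of ddm1 to wt, and 3 shared loci are too few to measure it.

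Sadhu elements, a family of non-autonomous retroposons, made up 2 of the 6 wt loci. SADHU1-1 (AT2TE16940, AT2G10410, Chr2 4006099 to 4007019, minus strand, annotated as a pseudogene exon) had 56 reads in wt, 60 in ddm1, 114 in ddm1 rdr6, 117 in ddm1 polV, 98 in replicate A and 10 in replicate B. SADHU5-1 (AT4TE03410, Chr4 660830 to 661723) had 11 reads in wt, 25 in ddm1 rdr6 and 26 in replicate B, and no model in the other libraries. AT3TE63065 (Chr3 15600424 to 15600798, in the pseudogene AT3G43690) was listed in every library, with 11 reads in wt and in ddm1 and 161 in replicate B. AT5TE72200 (Chr5 20048358 to 20049583), which lies antisense to an exon of the protein-coding gene AT5G49440, was also in every library, with 36 reads in wt and 35 in ddm1. AT5TE72580 (Chr5 20151140 to 20152570) overlapped an exon of the protein-coding gene AT5G49645 and had 11 reads in wt and no model in ddm1. AT4TE25700 (Chr4 6093447 to 6094930), in the transcribed pseudogene AT4G09644, had 11 reads in wt and 12 in replicate B, and was the only spliced wt model.

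Adding a mutation in either silencing pathway to ddm1 went with more TE models in these libraries. The ddm1 rdr6 library had 107 models (87.7 to 129), 2.23 times ddm1 (1.57 to 3.20, adjusted p = 4.26e-06, exact binomial test). The ddm1 polV library had 145 (122 to 171), 3.02 times ddm1 (2.17 to 4.28, adjusted p = 5.66e-12, exact binomial test). Most ddm1 loci were found again, 42 of 44 in ddm1 rdr6 and 40 of 44 in ddm1 polV, and 74 loci were shared by ddm1 rdr6 (92 loci) and ddm1 polV (127 loci). At the 3 loci shared with wt, reads were 106 in ddm1 and 197 in ddm1 rdr6 (mean log2 ratio 0.99, SE 0.25, against 1.37 for all TE reads), and were 151 in ddm1 polV (0.14, SE 0.84, against 1.83). When reads were thinned at random to the 1212 TE reads of ddm1, ddm1 rdr6 kept 51.3 models on average (46 to 57 in 95% of draws) and ddm1 polV 51.1 (46 to 57), against 48 in ddm1. The TE reads are the summed reads of these same models, and thinning to that sum removes any effect on the total. The thinned numbers therefore cannot tell more TE transcription from more depth. Without library totals, a ratio of model numbers cannot be separated from a ratio of depths.

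**Figure D1:**
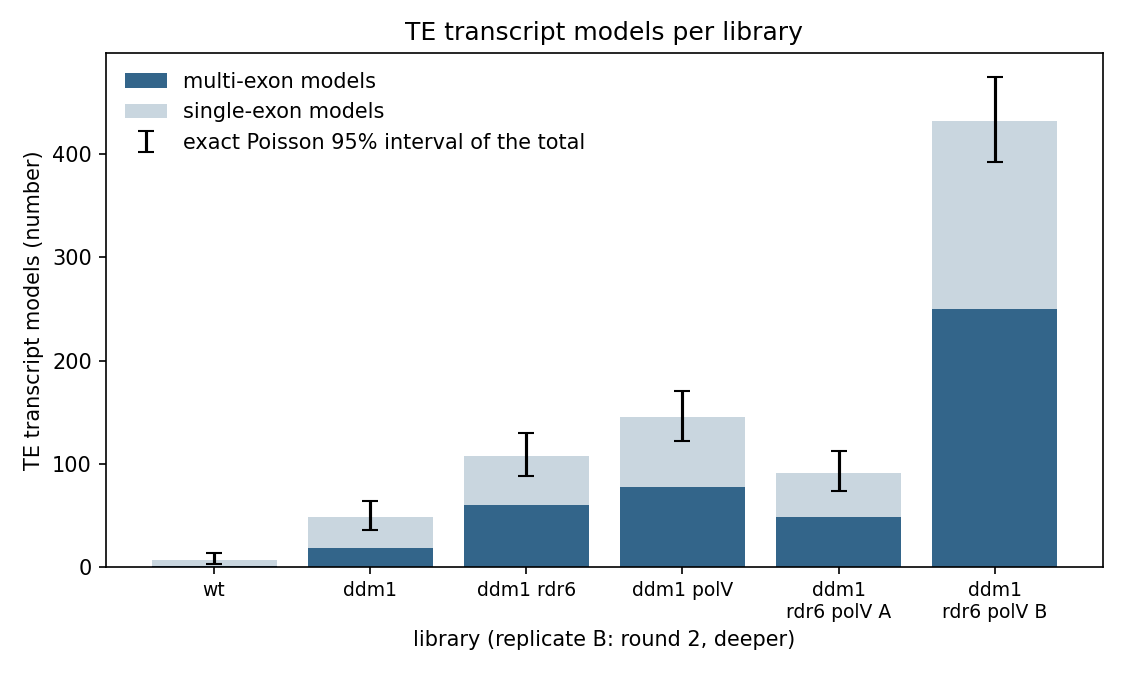
Number of TE transcript models in each library, split into multi-exon and single-exon models, with the exact Poisson 95% interval of the total. Numbers run from 6 in wt to 145 in ddm1 polV within round 1, and replicate B of round 2 holds 432.

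The triple mutant gave different answers in its replicates. Replicate A had 91 models (73.3 to 112), 1.90 times ddm1 (1.32 to 2.75, adjusted p = 0.000466, exact binomial test). That was 0.628 times ddm1 polV (0.477 to 0.821, adjusted p = 0.000622) and 0.850 times ddm1 rdr6 (0.636 to 1.14, adjusted p = 0.286, exact binomial tests). Replicate B had 432 models (392 to 475), 4.75 times replicate A (3.78 to 6.02, adjusted p = 2.8e-53, exact binomial test), and exceeded ddm1 polV 2.98-fold and ddm1 rdr6 4.04-fold. The direction against ddm1 polV therefore turned with the replicate, while a difference from ddm1 rdr6 was called only with B, and the replicates differed in round, PCR cycles and, per the labels, depth.

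Nearly every round 1 model had a counterpart in replicate B. All 91 models of replicate A overlapped a model of replicate B on the same strand (100%, Clopper-Pearson 95% interval 96.0 to 100). The shares were 95.8% for ddm1 (46 of 48), 97.2% for ddm1 rdr6 (104 of 107) and 95.2% for ddm1 polV (138 of 145), and none differed from that of replicate A (adjusted p = 0.176, 0.251 and 0.136, Fisher's exact test). Replicate B alone held 186 of the 344 loci, with a median of 15.5 reads, and 10 loci had no model there. When the overlap had to cover 80% of the longer model, the share of replicate A was 84.6%.

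Of the 344 loci, 31 were found in all 5 mutant libraries, of which 25 lay in pericentromeric bins and 6 did not. The fixed rule took 10 of them, with ties in model number broken by name. AT2TE19610 (Chr2 4727560 to 4731777, in the pseudogene AT2G11780) had 26 reads in ddm1, 49 in ddm1 rdr6, 272 in ddm1 polV, 137 in replicate A and 842 in replicate B. A replicate B model of 14 reads there had 7 exons and matched a CACTA (En/Spm) protein, while ddm1 held 0 models with such a match. AT4TE16900 (Chr4 3839420 to 3841614, outside annotated genes on its strand) had 186 reads in ddm1, 413 in ddm1 rdr6, 379 in ddm1 polV, 129 in replicate A and 565 in replicate B. AT4TE15820 (Chr4 3501702 to 3506699, in the pseudogene AT4G06566) had 39, 100, 280, 68 and 813 reads in the same order. AT1TE44450 (Chr1 13573914 to 13576541, in the pseudogene AT1G36190) had up to 5 exons and 24, 105, 84, 57 and 368 reads. The others were AT1TE45375, AT1TE44630, AT2TE15660, AT2TE20940, AT3TE53995 and AT4TE20245, with 11 to 22 reads in ddm1 and 63 to 465 in replicate B. None of the 10 had a model in wt.

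**Figure D2:**
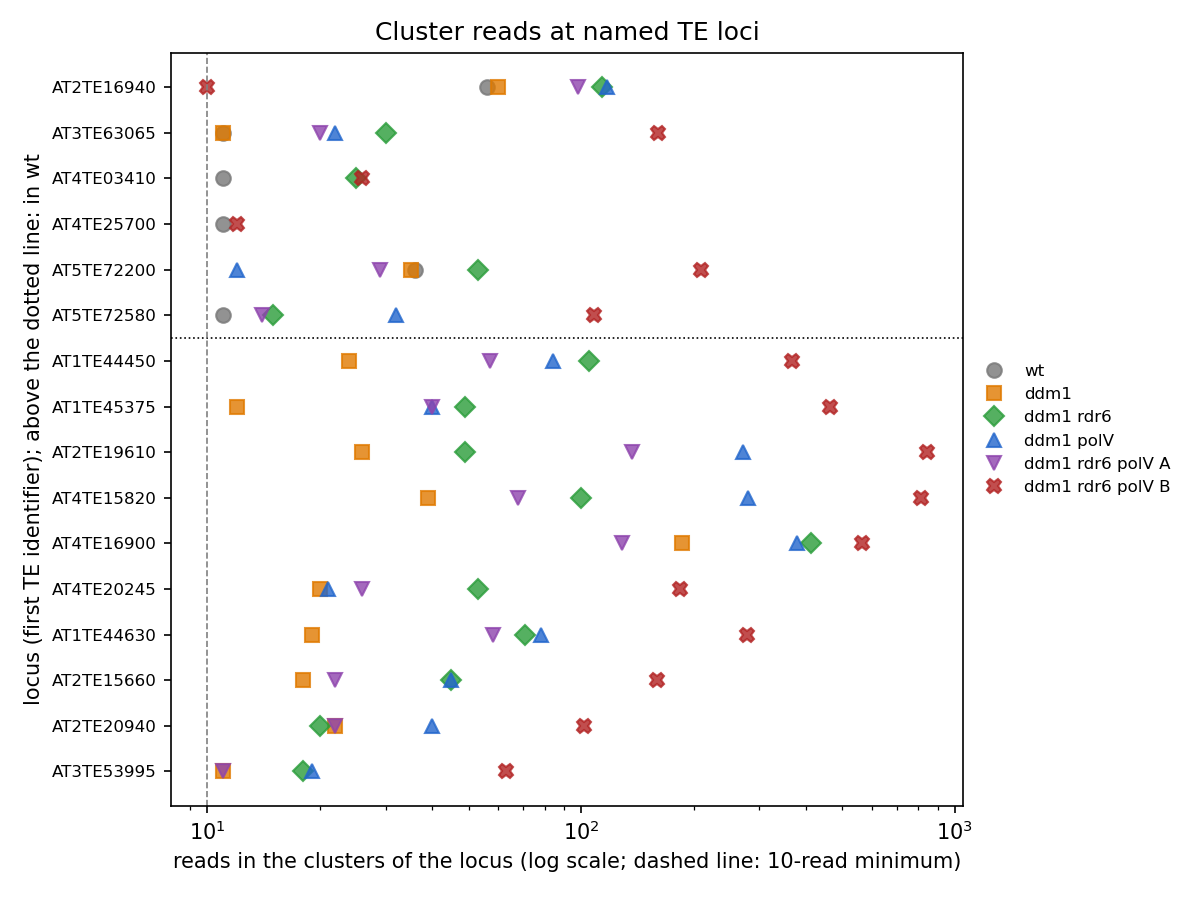
Reads in the clusters of each named locus (log scale) by library, for the 6 loci with a model in wt and 10 loci with a model in all 5 mutant libraries; a library without a point had no cluster of 10 reads. Replicate B has the most reads at each of the 10 mutant loci, and at AT2TE16940 it has 10 against 98 in replicate A.

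Read ratios at shared loci spread about as widely between the replicates of the triple mutant as between ddm1 and either double mutant, apart from a few outlying loci. The log2 ratio of replicate B to replicate A had an SD of 1.39 over 80 shared loci. The SD was 0.90 between ddm1 and ddm1 rdr6 (42 loci) and 1.23 between ddm1 and ddm1 polV (40 loci), while the interquartile ranges were 1.35, 1.26 and 1.23. Against 2 SDs of the replicate ratios (2.78), a limit widened by those outlying loci, 0 loci stood out between ddm1 and ddm1 rdr6, and 1 did between ddm1 and ddm1 polV. That locus was SADHU3-1 (AT3TE63935, Chr3 15813075 to 15814053), with 79 reads in ddm1, 159 in ddm1 rdr6, 14 in ddm1 polV, 85 in replicate A and 26 in replicate B. Between the replicates themselves 7 of the 80 loci passed this limit, SADHU3-1 among them (centred log2 ratio -3.88, against -3.63 between ddm1 and ddm1 polV). The replicates differed in round and, per the labels, depth, so the limit also holds any effect of these. A shared locus needed a model in both libraries, and the median ddm1 model had 18.5 reads. From so near the read minimum, a drop past the limit could not be seen. The few calls against ddm1 therefore do not show that reads at single loci were unchanged.

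Few models had a protein match, and most of those were in replicate B, where CACTA-like models were the most frequent of the classes searched. Gypsy, Helitron and SINE elements had no class of their own, so these values do not rank all superfamilies. CACTA-like models numbered 0 in ddm1, 4 in ddm1 rdr6, 10 in ddm1 polV, 2 in replicate A and 38 in replicate B. A class depends on the part of an element that a model covers. The ddm1 model at AT2TE19610, with 26 reads, had no match, although a replicate B model of that locus matched a CACTA protein. The 0 in ddm1 therefore does not show that no CACTA element was transcribed there. MuDR-like models numbered 2, 4, 8, 3 and 15 in the same order, and Copia-like models 0, 3, 2, 1 and 11. Models matching a reverse transcriptase of unstated type numbered 1, 1, 1, 0 and 3, and hAT-like models 1, 1, 1, 1 and 2. A mixed class of matches to gag-polyproteins or transposase-associated domain proteins numbered 0, 0, 1, 0 and 12. Most of its loci matched a transposase-associated domain protein, so this class is not a count of Gag-Pol elements. No model matched a protein named as LINE, which depends on how the reference proteins are named, and wt had no model with a match. None of 32 class tests passed after adjustment (Fisher's exact test, smallest adjusted p = 0.274), and 2 had an unadjusted p under 0.05. One of these was CACTA between the replicates (2 of 91 in A, 38 of 432 in B, p = 0.0293), and the other was the share without a match (92.3% in A, 81.0% in B, p = 0.00857, both exact).

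Grouped by sequence, 170 loci fell into 40 groups of at least 2 loci, and 174 loci stood alone. The largest group, that of AT1TE42225, was CACTA-like, with 20 loci of which 19 were spliced. It had 0 loci in ddm1, 2 in ddm1 rdr6, 6 in ddm1 polV, 1 in replicate A and 20 in replicate B. The group of AT2TE20940 had 13 loci, all pericentromeric and unspliced, and was already present in ddm1 with 7 loci, followed by 6, 9, 4 and 12. The group of AT5TE42190 had 11 unspliced pericentromeric loci, of which 10 were in replicate B and at most 2 in any round 1 library. A MuDR-like group of 4 loci, that of AT5TE53465, had all 4 in ddm1 polV and in replicate B and none in the other libraries. These loci had 10 to 13 reads each in ddm1 polV, near the 10-read minimum, so missing models elsewhere do not show absence. Another MuDR-like group, that of AT4TE67560, had 2 loci in ddm1, 3 in ddm1 rdr6, 4 in ddm1 polV, 3 in replicate A and 4 in replicate B. These numbers of loci were not tested by group.

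Spliced TE transcripts were common in the mutants. Multi-exon models made up 37.5% in ddm1 (18 of 48, Clopper-Pearson 95% interval 24.0 to 52.6), 56.1% in ddm1 rdr6 (60 of 107), 53.1% in ddm1 polV (77 of 145), 52.7% in replicate A (48 of 91) and 57.9% in replicate B (250 of 432, 53.1 to 62.6). None of the 4 pairs tested passed after adjustment (ddm1 against ddm1 rdr6, p = 0.0379 and adjusted p = 0.137, Fisher's exact test). With replicate B in place of A, the difference of 20.4 points from ddm1 passed (adjusted p = 0.0265, Fisher's exact test). The model with most exons among those found in more than 1 library lay at AT2TE26855 (Chr2 6566364 to 6571524, in the pseudogene AT2G15140), with 12 exons and 3060 nt in both replicates of the triple mutant and 12 exons in ddm1 polV. AT5TE51685 (CACTA-like, in the pseudogene AT5G36655) had 7 exons in ddm1 rdr6, ddm1 polV and replicate B. All 32 distinct introns of ddm1 were found in replicate B, as were 105 of 106 in ddm1 rdr6, 165 of 181 in ddm1 polV and 83 of 84 in replicate A. Introns had a median of 102 nt (quartiles 81 and 265 nt), and the longest was 180420 nt. No upper limit on intron length was set, and whether the longest introns reflect splicing was not tested.

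Median spliced length was 618.5 nt in ddm1, 738 nt in ddm1 rdr6, 723 nt in ddm1 polV, 639 nt in replicate A and 709.5 nt in replicate B. None of the 4 pairs tested passed after adjustment (permutation test, adjusted p from 0.172 to 0.680). The longest model was a single exon of 4933 nt in replicate B at AT5TE20395 (Chr5 5630298 to 5635230, in the pseudogene AT5G17125), a Copia-like element, with 10 reads. AT1TE52925 (hAT-like, in the pseudogene AT1G42705) was among the 5 longest in each round 1 mutant library, with 4 exons and 2560 to 2565 nt.

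TE transcripts of the mutants came mostly from pericentromeric regions. The share of models there was 85.4% in ddm1 (41 of 48), 80.4% in ddm1 rdr6, 81.4% in ddm1 polV, 78.0% in replicate A and 79.6% in replicate B, against 2 of 6 models in wt. These bins cover 21.4% of the nuclear genome. They were chosen for few protein-coding genes, and every model was paired with a TE. The share of annotated TEs in these bins was not computed, so these values do not show a preference among TEs. None of the 4 pairs tested (ddm1 against the other round 1 mutant libraries, and A against B) passed (adjusted p = 0.776 for each of these, Fisher's exact test). Of the 344 loci, 204 (59.3%) overlapped an annotated pseudogene on the same strand, 21 (6.10%) a protein-coding gene, and 116 (33.7%) no annotated gene. The annotation also gives TEs such as SADHU1-1 the type pseudogene, so this overlap does not tell TEs from decayed host genes.

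**Figure D3:**
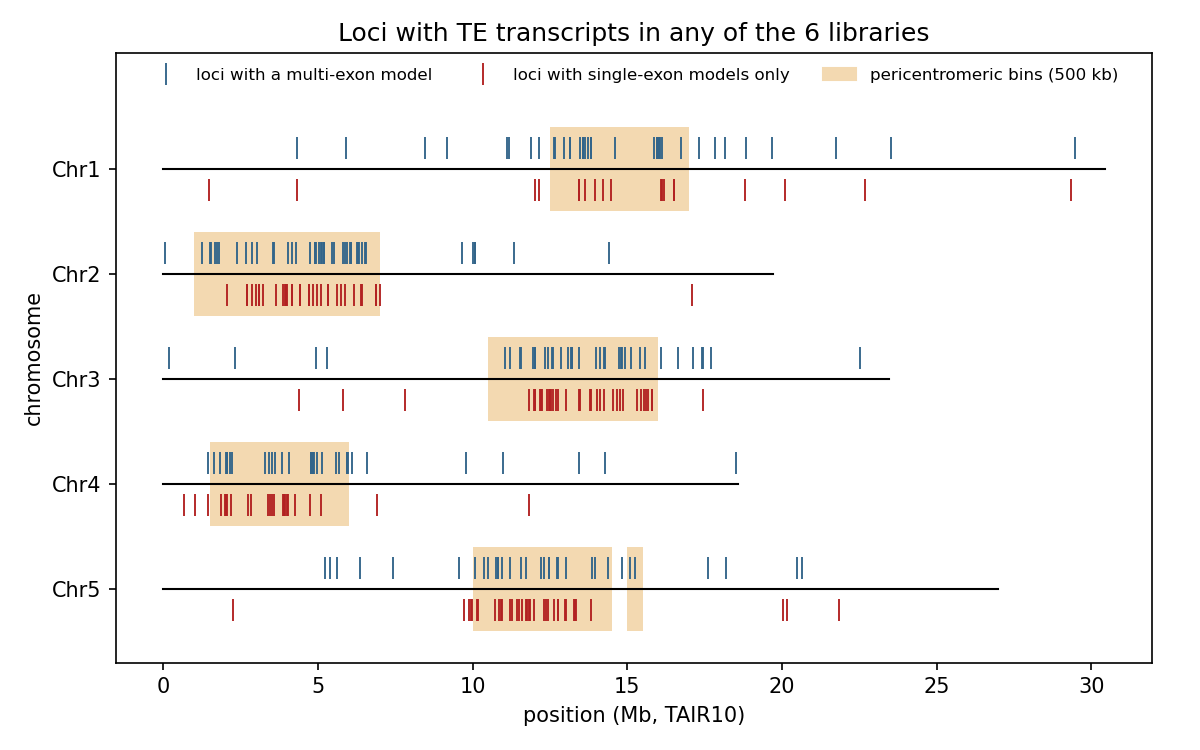
Position of the 344 loci with a TE transcript in any library along the 5 chromosomes (Mb), with loci that have a multi-exon model above each line, other loci below it, and pericentromeric bins shaded. Most loci lie within the shaded bins, which cover 21.4% of the nuclear genome. The share of annotated TEs in these bins was not computed.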

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

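The test of reads at the wt loci and the test of single-exon loci were chosen after the values were seen. For the tests that thin reads, the ranges were set beforehand, but how they were read was changed after the results were seen, as stated at each.

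In these libraries, the ratio of model numbers for each added mutation depended on the state of the other pathway and on which triple-mutant replicate was used. With Pol V intact, the ddm1 rdr6 library had 2.23 times the models of ddm1, and with Pol V mutated, replicate A had 0.628 times the models of ddm1 polV. The ratio of these ratios was 0.282 (p = 3.27e-09, Fisher's exact test on the 4 libraries). The same 0.282 describes the polV mutation, with a ratio of 3.02 when RDR6 is intact and 0.850 when it is mutated. With replicate B in place of A, it was 1.34 (p = 0.151, Fisher's exact test), so the difference was seen with A only. These p-values cover counting error between single libraries of unknown depth and do not test a genetic interaction.

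Fewer reads in replicate A are a candidate explanation for its fewer models. Thinning ddm1 polV at random to the 2317 TE reads of A left 84.5 models on average (79 to 90 in 95% of 1000 draws), so fewer TE reads would take the number below the 91 seen. The range set beforehand was missed by 1 model on the side of more models, and read strictly it would have excluded this explanation. It left out the counting error of A itself (73.3 to 112), so the question was left open. At 4 wt loci the mean log2 ratio of A to ddm1 polV was -0.0782 (SE 0.508) against -0.89 for all TE reads, and replicate B thinned to the reads of ddm1 polV gave 143.8 models against 145 seen, which by the rule set beforehand would have excluded the genotype but cannot show a genotype effect on total TE reads, so neither depth nor genotype was excluded.

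The spliced share was lower in ddm1 (37.5%) than in the other mutant libraries. Thinned to the 1212 TE reads of ddm1, the other round 1 mutant libraries kept mean shares of 50.6% to 58.6%, and 37.5% lay below all 3 of their 95% ranges, which by the rule set beforehand would have excluded fewer TE reads as the cause. The counting interval of ddm1 (24.0 to 52.6) overlaps these ranges, so it was left open, although replicate B of the other round, thinned alike, kept 61.1% (54.3 to 68), above that interval. A locus counted as spliced in a library if any of its models there had more than 1 exon. Of 42 loci shared by ddm1 and ddm1 rdr6, 3 differed, all spliced only in ddm1 rdr6 (p = 0.25, exact McNemar test). Between replicates A and B, of 1 genotype, 12 of 80 shared loci differed, all spliced only in B (p = 0.000488, exact McNemar test), so genotype and depth cannot be told apart here. Replicate B had 64 loci with 2 or more models and A had 10. More models per locus make a spliced call more likely under this rule, and unspliced models can remain at such loci.

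Some loci had fewer reads in replicate B than in A, although B had 7.38 times the TE reads. There were 8 such loci among 80, of which 6 were single-exon, including SADHU1-1 (98 in A, 10 in B) and SADHU3-1 (85 and 26). The median log2 ratio of B to A was 1.96 at single-exon and 2.42 at multi-exon loci, a difference of -0.46 (permutation p = 0.0329), but these loci include those that prompted the test, so it decides nothing about whether clustering kept fewer reads of single-exon models. At 56 loci of ddm1 polV and B that A did not hold, the difference was -0.34 (permutation p = 0.323), which leaves that explanation open. Both replicates have the same genotype, so no biological explanation was tested.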

How the results depend on the processing

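No alternative was added that changed a result: exonic overlap with replicate B, chosen after seeing the data, gave the same shares. Of 115 alternative values, 106 kept their direction and side of the threshold or, for shares with no test, stayed within the main value's 95% interval. Of these, 34 were identical to the main value, such as those for introns of at least 50 nt, which removed no intron, so they say nothing about stability. With replicate B in place of A, the triple mutant had 4.04 times the models of ddm1 rdr6 and 2.98 times those of ddm1 polV, against 0.850 and 0.628 with A alone. This turned the called direction against ddm1 polV, while A did not differ from ddm1 rdr6. With multi-exon models only, the ratio of ddm1 to wt was 18 in place of 8, from 1 such model in wt. The ratio of the triple mutant to ddm1 was 9 with B and 1.90 with A. The spliced share of the triple mutant was 20.4 points above ddm1 with B (adjusted p = 0.0265) and 15.2 with A. By mean in place of median length, B exceeded A by 196 nt (adjusted p = 0.0477, permutation test), and the difference of A from ddm1 turned from 20.5 to -15.8 nt, neither past the threshold. Also short of it, ddm1 rdr6 and ddm1 polV exceeded ddm1 by 213 and 204 nt by mean and by 263 and 190 nt by genomic span, against 119.5 and 104.5 nt, and A exceeded ddm1 by 107 nt by span, or B by 91 nt by median. Requiring 80% of the longer model, shares overlapping B were 81.2% in ddm1, 90.7% in ddm1 rdr6, 87.6% in ddm1 polV, 84.6% in A and 83.3% in wt (5 of 6, within its wide interval). The cause was not tested in these cases. Composition calls were 0 under every alternative. Libraries could not be paired by replicate because the genotypes share fewer than 2 replicate numbers. Loci shared by libraries were paired only in the McNemar tests and the read ratios. Without library totals, depth limits all comparisons of numbers between libraries, ddm1 against wt included, and loci under 10 reads are not seen.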

Other observations

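These observations were chosen after the values were seen. Long open reading frames went with splicing among the models of each mutant library. The tests below count several models of a locus, and similar copies, as independent, so their p-values overstate the evidence. Most round 1 models recurred in replicate B, so the libraries are not separate evidence. No test by locus or at matched length was run. A frame of at least 100 amino acids was present in 55.6% of multi-exon and 10% of single-exon models of ddm1 (adjusted p = 0.00162, Fisher's exact test), and in 68.3% and 12.8% of those of ddm1 rdr6 (adjusted p = 1.31e-08). In ddm1 polV the shares were 63.6% and 22.1% (adjusted p = 7.4e-07), in replicate A 47.9% and 14.0% (adjusted p = 0.00081), and in replicate B 58.0% and 15.4% (adjusted p = 3.13e-19, exact tests throughout). Median length was 695 nt for multi-exon and 579.5 nt for single-exon models in ddm1, 820 and 639 nt in ddm1 rdr6, 783 and 647.5 nt in ddm1 polV, 663.5 and 586 nt in replicate A, and 891 and 566 nt in replicate B. The wt library had 1 multi-exon model, of 448 nt, against a median of 921 nt for its 5 single-exon models. The longest frame, of 1404 amino acids, was in a single-exon model of replicate B.

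Of 16 annotated Sadhu elements, 2 had a model on their strand in wt, 2 in ddm1, 5 in ddm1 rdr6, 3 in ddm1 polV, 4 in replicate A and 8 in replicate B. QQS (AT3TE51150, AT3G30720, Chr3 12349040 to 12349861), a protein-coding gene of Arabidopsis that affects starch content, had a model in all 5 mutant libraries and none in wt. Its reads were 39 in ddm1, 15 in ddm1 rdr6, 21 in ddm1 polV, 11 in replicate A and 59 in replicate B.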
